A study of Homo sapiens with 16 samples.

How the data were processed

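Polyadenylated RNA was sequenced from HuT 78 cells, an established line of cutaneous T-cell lymphoma, in 16 libraries. Cells had received siRNA against the integrin genes ITGAV and ITGB3 (siINT), against the thyroid hormone receptor alpha gene THRA (siTR, named TRA in the labels and taken as this receptor) or a non-target sequence (siCT, the vehicle titles being taken as this arm), and then bexarotene, an agonist of the retinoid X receptors, or its control for 6 h in medium with thyroid hormone. The deposited values are raw read counts per gene without normalization, and the authors named STAR 2.4 and HTSeq on build hg19. The annotation, the strand setting and any filters were not given in the sources used here. The columns held whole numbers with unequal totals. The reference annotation at hand is of another build, so genes are named by the symbols in the deposited table and no coordinates are given. The named library kit does not mark the strand, so reads of the overlapping ends of THRA and NR1D1 cannot be told apart.

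The labels place 10 libraries in sequencing batch 1 and 6 in sequencing batch 2. All libraries of the control treatment with siCT and of bexarotene with siTR are in batch 2, and all others in batch 1. Bexarotene within siCT and within siTR is therefore confounded with batch, while bexarotene within siINT lies inside batch 1. Groups are written as siRNA_treatment, with ct for the control treatment and bexa for bexarotene. No label says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

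Of 55736 genes in the table, 34670 had any count and 16399 passed edgeR's filterByExpr by group (minimum count 10, minimum total 15). The genes tested held at least 99.88% of every library's counts. Counts were fitted in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood negative binomial models with TMM factors, 1 mean per group and all 16 libraries in 1 fit, which left 10 residual degrees of freedom. The tests were 2-sided, and the Benjamini-Hochberg false discovery rate was set at 0.05. The common biological coefficient of variation was 0.112. A further additive model held siRNA, treatment and batch, with 11 residual degrees of freedom and a common coefficient of variation of 0.154. The mean effect of bexarotene over siCT and siTR takes both contrasts with equal weight, so that a batch effect equal on the log scale in every group drops out, and the interaction sets the effect in siINT against this mean. Levels are given as CPM on TMM-scaled totals. Each SE of a log2 change is the absolute change divided by the square root of the F statistic of its test. It is only a rough guide where a group has very low counts. For the siRNA targets, CPM were compared by 2-sided exact permutation tests. Intervals of single counts are exact 95% Poisson intervals, and they and the floor of 3 counts cover counting error only.

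Gene lists written before the data were examined were tested by limma 3.58.1 camera with a preset correlation of 0.01, with an estimated correlation, and by fry, each adjusted over 33 lists of a comparison. The lists include markers of other cell types and of RNA quality. Named genes were set by a rule fixed at the same time. It takes the siRNA targets, the largest rises and falls among called genes with a mean of at least 5 CPM and no overlap between the groups, and up to 4 members of each list by the smallest p. Genes outside the rule are said to be chosen after their values were seen.

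The models were tested on simulated data of 16399 genes, of which 200 had been changed. These 200 were drawn only from genes above a minimum mean count, which left out genes of low count such as ITGAV. In the siINT comparison 86% of genes changed by 2-fold and 100% of those changed by 4-fold were recovered, with 7 false calls among 193. The corresponding shares were 84% and 100% for siINT against siCT under bexarotene, 75% and 99% for the interaction, and 97% and 100% for the comparison in batch 2. These shares were given by size of change, not by spread. In the real fit of all 16 libraries, genes called for bexarotene in siINT cells had a median coefficient of variation of 0.159, and other genes 0.0973. The shares therefore do not give the power for genes of such raised spread, nor for the genes of low count left out of the draw. Nor do they show that a comparison without calls is without change.

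The alternatives were other size factors (RLE, or library size alone), no filter on low counts, a filter of at least 1 CPM in 3 libraries, limma-voom, DESeq2 1.42.0, an absolute log2 fold change of at least 0.5, the compared groups alone, a replicate block from the label numbers, and each library left out in turn. Fits without 2 libraries that stood apart from their groups, fits of batch 1 alone without them, and a thinning of batch 2 to the depth of batch 1 were added after the data had been seen. No deposited column was left out.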

Results

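The deposited table gave read counts per gene for 16 libraries of HuT 78 cells. There were 3 libraries each of siCT_ct, siINT_ct, siINT_bexa and siTR_bexa, and 2 each of siCT_bexa and siTR_ct. Totals ran from 14133140 to 17438779 counts in the 10 libraries of batch 1 and from 20009448 to 28385555 counts in the 6 libraries of batch 2. Mitochondrially encoded genes took 4.21% to 8.46% of counts in batch 1 and 2.94% to 3.26% in batch 2. Batch 1 libraries detected 22069 to 22772 genes and batch 2 libraries 24481 to 25860. The first principal component held 57.6% of the variance and parted the batches, and the second held 18.4%.

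The siRNA target genes were read first, as a check of the labels. ITGAV, which codes for the integrin alpha-V chain, had low counts, 7 to 56 per library. In batch 1 its level was 1.01 ± 0.483 CPM (SD, n = 6) in the libraries labelled siINT and 1.04 ± 0.265 CPM (SD, n = 4) in the others, and the exact permutation p was 0.91, with 0.00476 the smallest it could give. ITGB3, the beta-3 chain, had 0 to 7 counts per library, too few to show a difference at this depth. THRA was at 35.3 ± 1.09 CPM (SD, n = 2) in the libraries labelled siTR_ct and 37.1 ± 4.39 CPM (SD, n = 8) in the other batch 1 libraries (exact permutation p = 0.578, smallest possible 0.0222). These others include libraries with bexarotene; against siINT_ct alone, at 41 ± 2.3 CPM (SD, n = 3), the log2 difference of siINT_ct minus siTR_ct was 0.218 (SE 0.113, adjusted p = 0.434), with THRA lower in both siTR_ct libraries (36 and 34.5 CPM). For ITGAV that difference was -0.454 (SE 0.408, adjusted p = 0.658). The 6 siINT libraries compared above pool both treatments. With bexarotene in siINT cells ITGAV had a log2 change of 1.15 (SE 0.333, edgeR adjusted p = 0.0782), which adds to their spread. In batch 2 THRA was at 10.6 ± 0.244 CPM (SD, n = 3) in those labelled siTR_bexa and 21.5 ± 2.29 CPM (SD, n = 3) in those labelled siCT_ct, a log2 change of -1.02 (SE 0.105, adjusted p = 1.14e-05). The exact permutation p of that difference was 0.1, the smallest that 3 against 3 libraries can give. A lower level of the siINT targets in the libraries labelled siINT was thus not called at this depth and number of libraries. A lower THRA in the 2 libraries labelled siTR_ct was not called either. Depth was not the limit there, with 481 to 675 counts of THRA per library in siTR_ct and siINT_ct. The 95% interval of its log2 difference of siINT_ct minus siTR_ct was -0.0345 to 0.47. A fall of THRA beyond 0.47 lies outside this interval, as the libraries are labelled. Groups are called by their labels throughout.

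**Figure D1:**
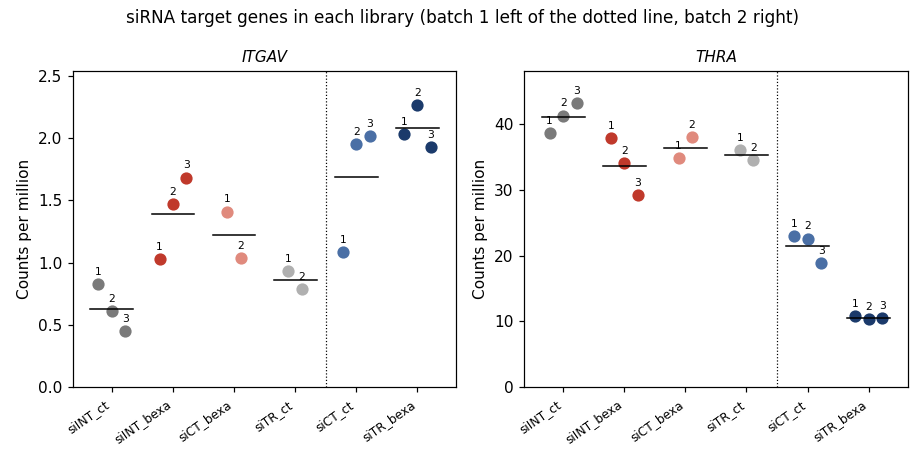
Levels of the siRNA targets ITGAV and THRA in CPM for each library, by labelled group, with points numbered by replicate, black lines at group means and a dotted line between the batches. THRA stood at 10.6 CPM on average in the libraries labelled siTR_bexa and at 21.5 CPM in those labelled siCT_ct.

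The effect of bexarotene in cells with integrin siRNA was asked by siINT_bexa against siINT_ct, the 1 arm with both treatments in 1 batch. Among the genes called, ABCA1, DHRS3 and SREBF1 were higher with bexarotene, and MYC, CCR4 and several T-cell genes were lower. ABCA1, the cholesterol exporter, was at 0.356 ± 0.273 CPM (SD, n = 3) in siINT_ct and 42.6 ± 11.7 CPM (SD, n = 3) in siINT_bexa, a log2 change of 6.84 (SE 1.44, adjusted p = 0.0332). GPR35, a G-protein-coupled receptor, went from 0.986 ± 0.384 CPM to 138.1 ± 23.4 CPM (SD, n = 3 each), a log2 change of 7.14 (SE 1.48). CCR4, a chemokine receptor of skin-homing T cells, fell from 70.1 ± 7.3 CPM to 14.7 ± 2.96 CPM (SD, n = 3 each), a log2 change of -2.26 (SE 0.466, adjusted p = 0.0332). In all, 473 genes were called, 321 higher and 152 lower, and 2773 had an unadjusted p under 0.05.

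Other large rises named by the rule included PALM (log2 change 7.61), SPIB (6.76), C2orf54 (5.83), PVRL1 (5.13), PANX2 (5.11), ELF3 (4.50) and PLCB3 (4.37), with SEs between 0.918 for ELF3 and 1.55 for PALM. SPIB and ELF3 code for transcription factors of the ETS family. The other large falls were HS3ST3B1 (-2.01), KCNMA1 (-1.69), ARID5B (-1.56), MEF2C (-1.55), FAM46C (-1.38), TRAT1 (-1.35), TRGC1 (-1.24) and TRGV5 (-1.17), together with the non-coding gene RP11-214O1.2 (-2.30). TRGC1 and TRGV5 are segments of the T-cell receptor gamma locus.

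Target lists of nuclear receptors that pair with the retinoid X receptor differed in how many members were called, and no list was called by camera with an estimated correlation. Fry called 6 lists, but not the fatty acid oxidation targets of PPAR (fry adjusted p = 0.149) or the NF-kB targets (fry adjusted p = 0.166). Of 11 tested sterol targets of LXR, 7 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 3.61e-07, adjusted p = 0.236 with an estimated correlation, fry adjusted p = 0.0457). Besides ABCA1, these included ABCG1 (log2 change 2.43, SE 0.473) and LPCAT3 (0.76). Of 17 retinoid receptor targets, 6 rose and 0 fell, and 12 rose adjusted over the list alone (camera adjusted p = 5.4e-09, adjusted p = 0.236 with an estimated correlation, fry adjusted p = 0.0457). DHRS3, a retinal reductase, rose by 2.81 on the log2 scale (SE 0.598), and TGM2 by 1.56. CYP26A1, which breaks down retinoic acid, had 3 counts over the siINT_ct libraries and 198 over the siINT_bexa libraries. Of 16 fatty acid oxidation targets of PPAR, 4 rose, among them ANGPTL4 (3.95), PLIN2 (1.13) and CPT1A (0.85), and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.02, adjusted p = 0.425 with an estimated correlation). Of 12 thyroid hormone receptor targets, 1 rose (SREBF1), with 3 adjusted over the list alone, and the camera adjusted p was 0.727.

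Of 13 fatty acid synthesis genes, 3 rose, SREBF1 (1.96, SE 0.441), ACACA (1.15) and SCD (0.85), and 6 adjusted over the list alone (camera adjusted p = 5.87e-05, adjusted p = 0.236 with an estimated correlation, fry adjusted p = 0.0457). SREBF1 is also in the LXR and thyroid lists, and SCD in the LXR list. Of 23 cholesterol synthesis genes, 1 rose (STARD4, 0.54), the same number adjusted over the list alone, with a camera adjusted p = 0.0402 and an adjusted p = 0.468 with an estimated correlation.

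Of 25 genes of MYC and ribosome biogenesis, 4 fell and 0 rose, and 18 fell adjusted over the list alone (camera adjusted p = 4.49e-14, adjusted p = 0.236 with an estimated correlation, fry adjusted p = 0.0457). MYC fell from 781.7 ± 50 to 527.2 ± 68.1 CPM (SD, n = 3 each), a log2 change of -0.57 (SE 0.124, adjusted p = 0.0332), with RRP12 (-0.59), POLR1B (-0.49) and GNL3 (-0.42). Of 25 T-cell identity genes 5 fell, among them TRAT1, TOX (-1.03) and LEF1 (-0.89), and 1 rose, with 7 and 4 adjusted over the list alone, and the camera adjusted p was 0.0528. No member was called among 36 genes of the G1/S phase and DNA replication or 35 of the G2/M phase and mitosis, by edgeR over all genes and adjusted over each list alone; the camera adjusted p was 0.704 for the first and 0.0157 for the second, the latter upward with an adjusted p = 0.684 with an estimated correlation. Of 12 cell-cycle inhibitors, CDKN1A (1.43, SE 0.313) and CDKN2D (1.07) rose (camera adjusted p = 0.108).

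Of 20 NF-kB targets 4 rose, ICAM1 (1.27), NFKBIA (0.81), LTA (0.71) and IRF1 (0.55), and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.000587, adjusted p = 0.425 with an estimated correlation). BCL2A1 rose (1.19), the 1 call among 10 anti-apoptotic genes (camera adjusted p = 0.0196, adjusted p = 0.236 with an estimated correlation), and BCL2L11, which promotes apoptosis, fell (-0.71), the 1 call among 23 such genes (camera adjusted p = 0.473). Among 23 cytokine and receptor genes IL2RB (1.34) and SOCS3 (2.05) rose, and among 9 chemokine receptor genes CCR7 (1.25) rose while CCR4 fell. Of 20 p53 targets 3 rose (CDKN1A, TP53INP1 1.82 and PLK3 1.86) and AEN fell (-0.60). Of 23 immediate early genes 4 rose, among them JUN (1.39), FOSL2 (1.45) and DUSP4 (1.14), and MYC fell. Of 26 focal adhesion genes 2 rose, among them SRC (1.23), and TLN2 fell (-0.35) (camera adjusted p = 0.029, adjusted p = 0.47 with an estimated correlation), and of 19 integrin genes ITGB7 rose (0.74). Of 29 interferon-stimulated genes 0 were called over all genes, while adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.0327, adjusted p = 0.468 with an estimated correlation). Among markers of other cell types, CD79A of B cells rose (1.69; the list's camera adjusted p = 0.0242, adjusted p = 0.236 with an estimated correlation), as did the cytotoxic genes PRF1 (0.94) and GNLY (0.86). The camera adjusted p was 0.675 for the cytokine list, 0.36 for the chemokine receptors, 0.803 for the p53 targets, 0.304 for the immediate early genes, 0.181 for the integrins and 0.104 for the cytotoxic markers. Adjusted over the list alone, risers and fallers were 3 and 2 among cell-cycle inhibitors, 5 and 1 among anti-apoptotic and 5 and 2 among pro-apoptotic genes, 3 and 2 among cytokine genes, 1 and 3 among chemokine receptors, 3 and 3 among p53 targets, and 5 and 2 among immediate early genes. They were 4 and 1 among focal adhesion genes and among integrins, 3 and 0 among B-cell markers and 2 and 0 among cytotoxic markers. The thyroid, p53, pro-apoptotic and G1/S lists had a median and a mean log2 change of different sign, and none of these was called by camera. Genes named as risen or fallen in this comparison were called over all genes, with edgeR adjusted p-values between 0.0332 and 0.0499. Genes counted only when adjusted over a list alone were not called over all genes.

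Without any 1 of the 6 siINT libraries edgeR called 0 genes, the smallest adjusted p with all libraries being 0.0332. Without the libraries labelled siCT_bexa replicate 2 and siTR_ct replicate 2, a fit chosen after the data were seen called 1451 genes (836 higher, 615 lower), including all 473 in the same direction; with these 2 and any 1 siINT library left out, 956 to 1394 were called, including 458 to 469 of the 473 in the same direction.

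These 2 libraries stood apart from their own groups in genes called for bexarotene in siINT cells. Between the counts of 2 libraries of a group, the chi-square per degree of freedom was 23.26 for siCT_bexa and 34.96 for siTR_ct. It was 20.66 for siINT_ct replicates 2 and 3 and 22.89 for siCT_ct replicates 1 and 3. For replicates 1 and 2 it was only 2.928 in siINT_ct and 2.016 in siCT_ct. Whether such close pairs were separate cultures is not known. Replicate 3 of these groups thus also differed from others of its group over the genes at large. ABCA1 was at 24.8 CPM in siCT_bexa replicate 1 and 0.403 CPM in siCT_bexa replicate 2, and at 0.133 CPM in siTR_ct replicate 1 and 53.5 CPM in siTR_ct replicate 2. DHRS3 was at 112.6 and 19.3 CPM in siCT_bexa and at 12.5 and 110.9 CPM in siTR_ct. CCR4 was at 18.2 and 65.8 CPM in siCT_bexa and at 70.6 and 12.6 CPM in siTR_ct. On a scale over the 473 genes with 0 at the siINT_ct mean and 1 at the siINT_bexa mean, the library labelled siCT_bexa replicate 2 had a median position of 0.1 and that labelled siTR_ct replicate 2 of 1.029, against 0.874 and 0.013 for replicate 1 of each group. The 473 genes were called with these libraries in the fit of the spread but not in the contrast. Their values thus entered the choice of genes through the spread, but not the means that set the ends of the scale.

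**Figure D2:**
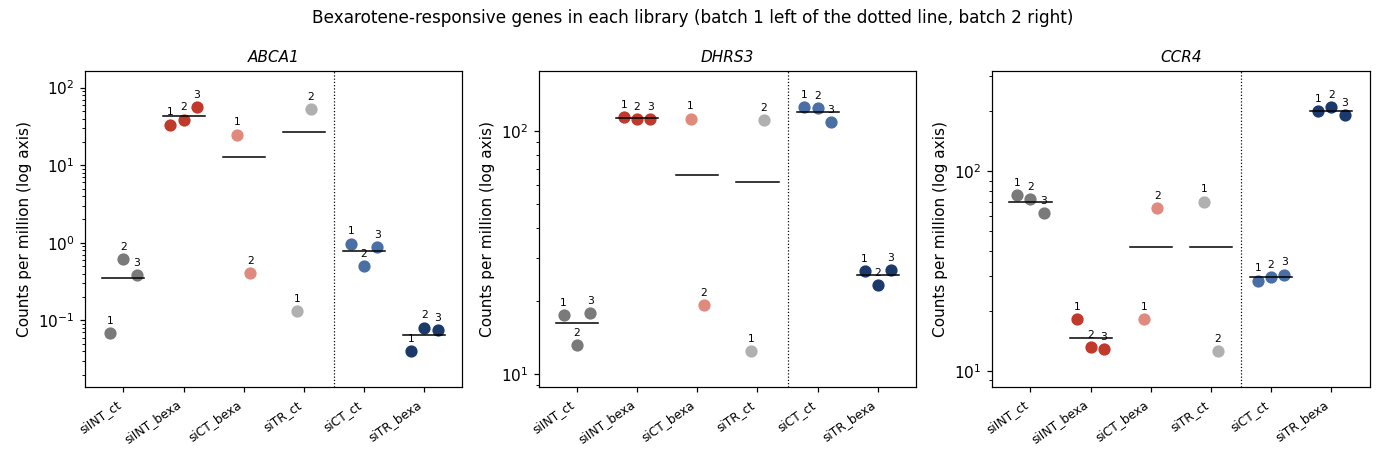
Levels of ABCA1, DHRS3 and CCR4 in CPM on a log axis for each library, by labelled group, with points numbered by replicate, black lines at group means and a dotted line between the batches. The libraries labelled siCT_bexa replicate 2 (ABCA1 0.403 CPM) and siTR_ct replicate 2 (53.5 CPM) lie away from replicate 1 of their groups.

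**Figure D3:**
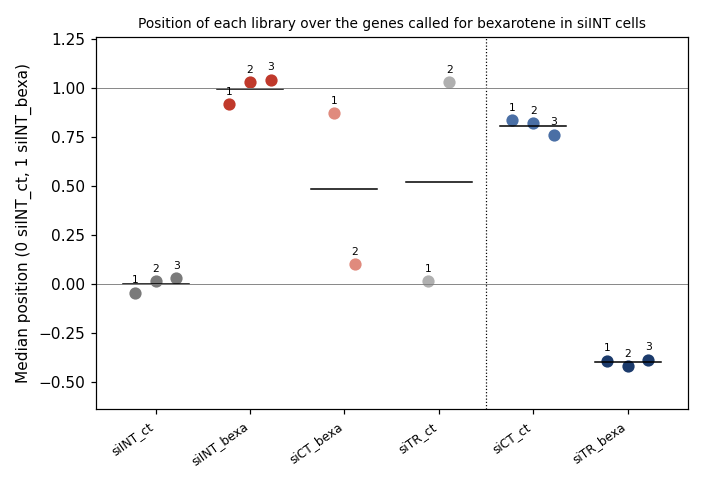
Median position of each library over the 473 genes called for bexarotene in siINT cells, with 0 at the siINT_ct mean and 1 at the siINT_bexa mean, and a dotted line between the batches. In batch 2 the libraries labelled siCT_ct lie between 0.763 and 0.836 and those labelled siTR_bexa between -0.42 and -0.386.

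Whether integrin siRNA changed expression under bexarotene was asked by siINT_bexa against siCT_bexa, within batch 1. ABCA1 was at 42.6 ± 11.7 CPM (SD, n = 3) in siINT_bexa and at 24.8 and 0.403 CPM in the siCT_bexa libraries. DHRS3 was at 112.9 ± 1.43 CPM (SD, n = 3) in siINT_bexa and at 112.6 and 19.3 CPM in siCT_bexa. No gene was called by edgeR, and 726 had an unadjusted p under 0.05; DESeq2 and limma-voom also called 0. Camera called 12 lists, among them the LXR targets (adjusted p = 1.33e-05) and the retinoid targets (4.32e-06) upward and MYC and ribosome biogenesis downward (1.59e-08), each with an adjusted p = 0.452 with an estimated correlation. Integrin genes were also called upward (0.00299, again adjusted p = 0.452 with an estimated correlation). Without the libraries that stood apart the median log2 change went from 0.37 to 0.165 for the LXR targets, from 0.503 to 0.0456 for the retinoid targets and from -0.199 to -0.0329 for MYC and ribosome biogenesis, so these 3 shifts depend on those libraries. Those of the other called lists kept their direction, but in this fit siCT_bexa was replicate 1 alone. The integrins went from 0.136 to 0.315, hypoxia and glycolysis from 0.076 to 0.444 and mitochondrially encoded genes from -0.198 to -0.395. Cholesterol synthesis went from 0.114 to 0.21 and fatty acid synthesis from 0.343 to 0.281. With an estimated correlation camera called none of the 12 lists (adjusted p between 0.452 and 0.69). Without the low-count filter edgeR called 281 genes, and without siCT_bexa replicate 1 it called 5.

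Integrin and receptor siRNA were compared without bexarotene by siINT_ct against siTR_ct, within batch 1. ABCA1 was at 0.356 ± 0.273 CPM (SD, n = 3) in siINT_ct and at 0.133 and 53.5 CPM in the siTR_ct libraries, and GPR35 at 0.986 ± 0.384 CPM (SD, n = 3) against 0.464 and 118.1 CPM. No gene was called by edgeR, with 2066 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 24. Camera called 6 lists, with MYC and ribosome biogenesis upward and mitochondrially encoded genes downward (adjusted p = 6.9e-07 for both, and adjusted p = 0.898 with an estimated correlation for both) and the LXR and retinoid targets downward (0.0233 and 0.0225, and adjusted p = 0.917 with an estimated correlation for both). Without the libraries that stood apart the median log2 change of MYC and ribosome biogenesis went from 0.178 to 0.011, that of the LXR targets from -0.583 to 0.159 and that of the retinoid targets from -0.494 to 0.23, so these shifts depend on those libraries, while that of the mitochondrially encoded genes went from -0.473 to -0.766. Mitochondrially encoded genes took 8.46% and 5.56% of counts in siTR_ct, and 4.32%, 4.21% and 7.29% in siINT_ct. Without the libraries that stood apart siTR_ct was replicate 1 alone, the library at 8.46%. The count depends on single libraries, being 463 without siTR_ct replicate 1 and 1 without siINT_ct replicate 3, and it was 934 without the low-count filter and 357 in batch 1 alone without the 2 libraries that stood apart.

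Batch 2 allowed siTR_bexa against siCT_ct alone, a comparison in which siRNA and treatment change together. Most genes that rose with bexarotene in siINT cells were lower here in the libraries labelled siTR_bexa, and most that fell there were higher. Of the 473 genes called there, 465 had the opposite sign here and 8 the same sign. CCR4 was at 200.3 ± 9.2 CPM (SD, n = 3) in siTR_bexa and 29.4 ± 1.02 CPM (SD, n = 3) in siCT_ct, a log2 change of 2.77 (SE 0.444, adjusted p = 0.000363). CD38, an ectoenzyme induced by retinoids, was at 17.4 ± 0.594 CPM in siTR_bexa against 224.7 ± 6.58 CPM in siCT_ct (SD, n = 3 each), a log2 change of -3.69 (SE 0.445, adjusted p = 3.63e-05). In all 3038 genes were called, 1330 higher and 1708 lower, with 5090 at an unadjusted p under 0.05. The balance depends on the scaling, being 1644 higher and 1509 lower with library size alone.

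Other large rises were HS3ST3B1 (log2 change 2.86), ARID5B (2.73), MEF2C (2.72), THEMIS (2.54), PDE4D (2.30) and PDE4B (2.11), and large falls were CREB3L3 (-7.22), FGR (-6.80), SPIB (-6.42) and ASB2 (-6.17). C2orf54 had 1037 counts over the siCT_ct libraries and 0 over the siTR_bexa libraries, which allows up to 3 counts. Of 17 retinoid targets 10 fell and 0 rose, and adjusted over the list alone 11 fell and 1 rose (camera adjusted p = 0.00108, adjusted p = 0.564 with an estimated correlation, fry adjusted p = 0.028), including TGM2 (-3.77). Of 11 LXR targets 4 fell and 0 rose, and 5 fell adjusted over the list alone (camera adjusted p = 0.0408, adjusted p = 0.691 with an estimated correlation). Of 20 NF-kB targets 13 fell and 2 rose (camera adjusted p = 3.21e-05, adjusted p = 0.564 with an estimated correlation), with ICAM1 at -2.27 and BCL3 at -2.05, and the counts were equal adjusted over the list alone. Of 12 thyroid hormone receptor targets 5 fell and 2 rose, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0329, adjusted p = 0.564 with an estimated correlation), with FURIN (-2.72) and HR (-1.75) among the falls and TXNIP (0.52) among the rises.

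Of 25 genes of MYC and ribosome biogenesis 9 rose and 0 fell, with MYC at 0.82 (SE 0.124), and of 26 genes of hypoxia and glycolysis 11 rose and 0 fell, with the hexokinase gene HK2 at 1.28 (SE 0.24); 12 and 14 rose adjusted over the list alone, and both lists had a camera adjusted p = 3.21e-05 and an adjusted p = 0.564 with an estimated correlation. Of 25 T-cell identity genes 9 rose and 5 fell, with TRAT1 at 1.94 and CD52 at -1.58, and 10 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0408, adjusted p = 0.564 with an estimated correlation). Of 10 anti-apoptotic genes 6 fell, among them BCL2A1 (-1.60) and MCL1 (-0.70), and 1 rose, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.0292, adjusted p = 0.564 with an estimated correlation). IL7R rose (1.52) and SOCS3 (-4.48), PLK3 (-3.90) and KLF2 (-3.48) fell. The count was 1948 without siCT_ct replicate 1, 1976 without siCT_ct replicate 2 and 2015 without siTR_bexa replicate 1.

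Calls of this comparison were set against those of bexarotene in siINT cells, which uses other libraries. Of the 321 genes that rose in siINT cells, 273 were called lower in siTR_bexa, where 33.4 would be shared if the calls were independent, and 0 were called higher (26 if independent). Of the 152 that fell, 122 were called higher (12.3 if independent) and 0 lower (15.8 if independent). Across the 16399 genes the log2 changes had a Pearson correlation of -0.63 and a Spearman correlation of -0.428; genes are not independent replicates. Without the 2 libraries that stood apart, 693 of 836 risers were called lower and 480 of 615 fallers higher, against 5 and 5 called in the same direction.

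**Figure D4:**
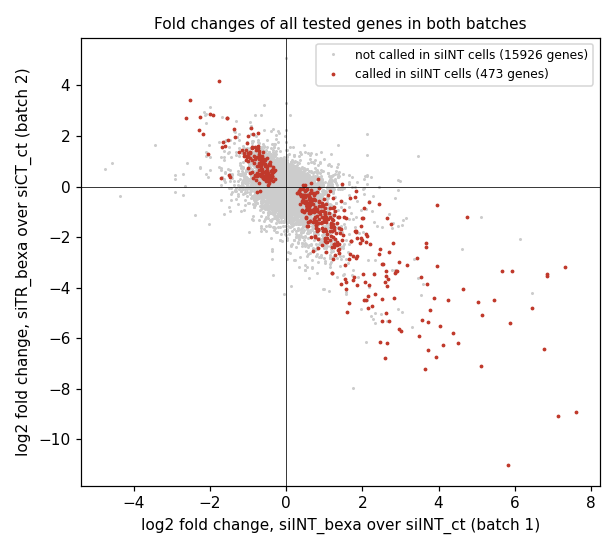
Log2 change with bexarotene in siINT cells against the log2 difference siTR_bexa minus siCT_ct for each gene tested, with the 473 genes called for bexarotene in siINT cells marked among all 16399. Of the marked genes, 465 had opposite signs on the axes and 8 the same sign.

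The mean effect of bexarotene over siCT and siTR cells, in which an equal batch effect drops out, called 800 genes, 261 higher and 539 lower. Genes named above were among them with the directions of batch 2: FGR (-3.53), CREB3L3 (-3.52), SPIB (-3.33) and ELF3 (-3.55) were lower, and HS3ST3B1 (1.39), CCR4 (1.39, SE 0.344), MEF2C (1.33), ARID5B (1.21), PDE4B (1.16) and PDE4D (1.14) were higher. Of 17 retinoid targets 3 fell and 0 rose, and 7 fell adjusted over the list alone (camera adjusted p = 0.000701, adjusted p = 0.815 with an estimated correlation). Without the libraries that stood apart 3 fell and 1 rose, and the median log2 change of this list went from -0.609 to 0.0106 and that of the LXR targets from -0.478 to 0.166, so the fall of these lists as groups depends on those libraries. In the fit with all libraries 182 of the 321 genes that rose in siINT cells were called lower (10.6 if independent). The part of this contrast inside batch 1, siCT_bexa against siTR_ct, called 0 genes by edgeR, and the part inside batch 2 the 3038 above, so the relation was called within batch 2 and not within batch 1. Each arm of the batch 1 part holds 1 of the libraries that stood apart. The count was 276 without siTR_ct replicate 2, 339 without siCT_bexa replicate 2, 507 without siTR_bexa replicate 1, 527 without siCT_ct replicate 2, 1277 without siCT_bexa replicate 1, 1630 without siTR_ct replicate 1 and 193 without both libraries that stood apart.

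Whether bexarotene acted differently with integrin siRNA was asked by the interaction, the effect in siINT cells minus that mean. SREBF1 (2.88, SE 0.556), DHRS3 (3.87, SE 0.738), SPIB (10.09, SE 1.63) and GPR35 (11.72, SE 1.87) had positive log2 interactions, and CCR4 (-3.65, SE 0.58), HS3ST3B1 (-3.39, SE 0.494) and MYC (-1.08, SE 0.158) negative ones. In all 1945 genes were called, 1112 positive and 833 negative, or 1006 and 1021 with library size alone. Of 17 retinoid targets 11 were positive and 0 negative, of 11 LXR targets 6 and 0, and of 25 genes of MYC and ribosome biogenesis 0 and 16 (12 and 1, 9 and 0, and 0 and 19 adjusted over the list alone; camera adjusted p = 1.1e-07, 2.23e-05 and 6.07e-13, and adjusted p = 0.447 with an estimated correlation for each). With the part inside batch 1 in place of the mean 0 genes were called by edgeR and with the part inside batch 2 there were 3324, so edgeR made these calls too within batch 2 and not within batch 1. Without the libraries that stood apart the positive and negative calls were 5 and 0 among retinoid targets, 5 and 0 among LXR targets and 0 and 10 among genes of MYC and ribosome biogenesis. The count was 1278 without siINT_bexa replicate 2 and 1088 without both libraries that stood apart.

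Bexarotene within siCT and within siTR could not be told apart from sequencing batch. The first contrast called 7479 genes (3626 higher, 3853 lower) and the second 8267 (4157 higher, 4110 lower, or 4061 and 4202 with RLE size factors). IGFBP2, which binds insulin-like growth factors, was lower by -7.31 (log2) with bexarotene in siCT cells and higher by 9.10 in siTR cells. TBX21, the T-helper 1 transcription factor, was higher by 4.07 in the first and lower by -8.32 in the second, and SDK2 went the other way (-5.14 and 5.59).

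In the additive model, which takes the effect of bexarotene as equal in all siRNA arms, edgeR called 0 genes for bexarotene, with 518 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 3. ITGAV had a log2 change of 0.65 (SE 0.201) and THRA of -0.41 (SE 0.0667, adjusted p = 0.292). Without the 2 libraries that stood apart 82 genes were called, and without the low-count filter 67. The batch term called 9460 genes, 4781 higher in batch 2 and 4679 lower, or 4714 and 4725 with RLE size factors. IGFBP2 was at 155.7 and 211.5 CPM on average in the batch 2 groups and at 0.386 to 1.12 CPM in the batch 1 groups, a log2 difference of 8.13 (SE 0.253, adjusted p = 1.68e-11). ARHGEF10 (5.76), SDK2 (5.35) and CAV1 (3.64), the gene of caveolin-1, were also higher in batch 2, and IFNG (-5.27), KLRB1 (-4.87), CD9 (-4.80) and TBX21 (-5.32) were lower.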

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

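The tests of exchanged or mixed libraries, of exchanged labels or a turned response in batch 2 and of another cell line were chosen only after the result was seen, and the thinning of batch 1 was chosen after the positions and totals were known. The other tests, of depth between the batches and of other splits of the libraries, were set before their results.

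As the libraries are labelled, the effect of bexarotene differed between siINT cells and the mean of siCT and siTR cells for 1945 genes by the test of the difference itself. The log2 interaction was 2.88 for SREBF1, 3.87 for DHRS3, -3.65 for CCR4 and -1.08 for MYC. With the part of the mean inside batch 1 edgeR called 0 such genes, and both patterns below enter this difference. It is a difference between labelled groups and does not by itself show that bexarotene acted differently with integrin siRNA.

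The library labelled siCT_bexa replicate 2 lay at the level of untreated siINT cells and that labelled siTR_ct replicate 2 at the level of treated ones, with median positions of 0.1 and 1.029. RNA of treated and untreated cells mixed in about equal shares in both libraries was taken to place both between 0.25 and 0.75. The position of 1.029 lies outside this by more than the spread of the siINT libraries. Those ran from -0.044 to 0.029 and from 0.919 to 1.043. Unequal shares could place a library nearer either end, so these bounds do not decide about them. Depth was read in 2 ways: the totals of these libraries, 17438779 and 14133140, lay just outside the 14455720 to 16658464 of the other 8 batch 1 libraries while their mitochondrial shares lay inside, and with all of batch 1 thinned to the lowest total the positions were 0.095 and 1.027, so depth does not account for them. An exchange of the treatments of these 2 libraries, at any step from culture to label, is a candidate explanation that stays open: it needs a partner out of place in the other group, which each has, but the positions 0.1 and 1.029 are the observation it was drawn from and lend it no further support. No biological explanation was tested, and no library was moved to another group.

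In batch 2 the genes called for bexarotene in siINT cells went the other way, with 465 of 473 of opposite sign. A candidate explanation is that the treatments of the 2 batch 2 groups are exchanged. In that case siCT_ct minus siTR_bexa would hold a bexarotene effect together with any difference between the siRNAs. Over the 473 genes its median size was 1.227 times the bexarotene effect in siINT cells (quartiles 0.841 and 1.714). The 7 called LXR targets had a median of 0.506. Summed counts in siCT_ct and siTR_bexa were 59 and 5 for ABCA1, 960 and 602 for ABCG1, and 7815 and 14 for GPR35. In siINT_bexa and siINT_ct they were 1957 and 17, 4740 and 893, and 6307 and 45. ABCA1 and ABCG1 in siCT_ct thus lay far below siINT_bexa, in spite of deeper libraries, and GPR35 did not. Whether the batch lowers ABCA1 and ABCG1 could not be separated. The ratio over the 473 genes is positive through the same opposite signs that led to this explanation, so it lends no further support to an exchange of treatments. An exchange of the whole labels, siRNA included, cannot be told apart from this, since THRA was lower in the libraries labelled siTR_bexa (-1.02), as an unexchanged siRNA label would have it, but in batch 1 its log2 difference of siINT_ct minus siTR_ct was 0.218 (SE 0.113, adjusted p = 0.434), so that it does not clearly mark the siRNA there. That receptor siRNA itself turns the response round stays open as the biological explanation in the design, because no siTR library of the other treatment lies in batch 2; the same holds for a difference in the cells of the 2 batches. The values per library cannot decide between these, and the comparison is given by its labels.

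In the additive model 9460 genes differed between the batches. Greater depth of batch 2 does not account for this, since 9273 were called after its libraries were thinned to the median total of batch 1. An unrelated cell line in batch 2 is argued against by the T-cell receptor segments TRAV8-6 (94.9 CPM in batch 1 and 115.4 in batch 2), TRAV20 (10.3 and 16.7), TRGV5 (12.8 and 9.11) and TRBV9 (2.79 and 7.10). The lowest level in the other batch was 2.792 CPM. The bounds of this test, 5 and 2 CPM, were set after the values were seen. A line derived from the same cells would share these segments, so the test cannot decide about such a line. Culture, library preparation and sequencing between the batches were not separable. Of 60 splits of 10 against 6 libraries 1 gave as many genes, the real one, and the highest other split gave 22. This argues against a chance split of single libraries. The splits break up the groups, each of which lies within a batch, so chance between whole groups was not tested.

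For bexarotene in siINT cells 1 of the 10 splits of the 6 libraries gave as many genes, the real one with 473, and the highest other gave 0; for the comparison in batch 2 it was again 1 of 10, the real one with 3038, and the highest other gave 0. In both, 10 splits are too few for a share under 0.05. For bexarotene in the additive model the real count was 0. All 60 of 60 splits of treatment within siRNA reach it whatever the data, so they decide nothing about chance. The highest other gave 205, a value that depends on which 60 splits were drawn. Whether it reflects a structure of the samples was not tested.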

How the results depend on the processing

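The fits without the libraries that stood apart, and of batch 1 alone without them, were chosen only after the result was seen, and the cause of a change was not tested unless given. Bexarotene in siINT cells (473 calls) gave 1301 without the low-count filter, 290 by limma-voom, 874 by DESeq2, 1217 with its 2 groups alone, 0 by edgeR with the replicate block, 0 to 0 with each library left out, 1451 without both apart libraries and 1226 in batch 1 alone. The 2 apart libraries raise the fitted spread of these genes, whose median coefficient of variation was 0.159 with 16 libraries and 0.0799 with 14, and the smallest adjusted p of 0.0332 fell to 1.44e-13 without them; fewer samples then end the calls when another library leaves. The siINT_ct and siINT_bexa libraries placed in the same block had deviations from their group means that correlated at 0.04, 0.01 and -0.16. These are too few pairs to decide whether the libraries are paired. Both apart libraries fell in the same block. siINT against siCT under bexarotene (0) gave 281 without the filter, 1 without both, and 0 to 5 with each library left out. siINT against siTR (0) gave 934 without the filter, 24 by DESeq2, 1 with its groups alone, 357 in batch 1 alone, and 0 to 463.

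The comparison in batch 2 (3038) gave 1948 to 3751 with each library left out. The mean over siCT and siTR (800) gave 509 at a log2 change of 0.5 or more, 1390 without the filter, 432 with the block, 0 in batch 1, 3038 in batch 2, 193 without both, and 276 to 1630. The interaction (1945) gave 0 and 3324 with the parts in batch 1 and batch 2, 1088 without both, and 1278 to 2781. The siCT contrast confounded with batch gave 4949 at a log2 change of 0.5 or more and 5499 to 6967, the siTR one 6580 to 7483, bexarotene in the additive model (0) 67 without the filter, 3 by DESeq2, 82 without both and 0 to 0, and batch 5623 at a log2 change of 0.5 or more and 8436 to 9573. Size factors (RLE or library size alone) and the stricter filter kept every count named here within 1.5 times. The block could not be fitted for the confounded contrasts and batch. A lone library left in a group was assumed to vary like the other groups.

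With an estimated correlation 0 of 12 lists were called by camera in siINT cells and 0 of 12 in batch 2; fry called 6 and 12. At a rate of 0.1, opposite calls rose from 395 to 782 and, for the mean, from 252 to 491. ABCA1 for batch, -5.66, ran from -7.21 to 2.35 with each library left out, turning without siTR_ct replicate 2, and was 1.37 without both, and ITGAV for siINT against siCT, 0.20, ran from -0.0117 to 0.428, turning without siCT_bexa replicate 2, and was -0.0113 without both and -0.0118 in batch 1 alone. Depth limits ITGB3 and other genes near 3 counts per library, which is 0.105 to 0.215 CPM.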

Other observations

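The receptors and marker lists here were planned, and RARG, RXRA and NR1D1 were named only after the result was seen. RARG, a retinoic acid receptor, was lower in the libraries labelled siTR_bexa than in those labelled siCT_ct, with a log2 change of -2.12 (SE 0.134, adjusted p = 2.98e-07), and had a log2 change of 0.20 (SE 0.123, adjusted p = 0.442) with bexarotene in siINT cells. RXRA, a receptor that bexarotene binds, had a log2 change of -0.88 (SE 0.233, adjusted p = 0.0547) in siINT cells and 0.32 (SE 0.224, adjusted p = 0.362) in batch 2. NR1D1, a repressor of the circadian clock that overlaps THRA, had a log2 change of -1.01 (SE 0.257, adjusted p = 0.0477) in siINT cells and 0.75 (SE 0.251, adjusted p = 0.0492) in batch 2.

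Between the batches, 17 of 23 cholesterol synthesis genes were higher in batch 2 and 2 lower, with HMGCS1 at 1.74, SC5D at 1.53 and INSIG1 at 1.51 (camera adjusted p = 2.43e-06, adjusted p = 0.254 with an estimated correlation). Of 12 heat shock genes 10 were lower in batch 2, among them HSPA1B (-2.11) and HSPA1A (-1.84), and of 9 cytotoxic markers 7 were lower, among them NCR1 (-5.37), GNLY (-2.69) and GZMB (-2.36) (camera adjusted p = 0.000232 and 0.00239, adjusted p = 0.282 with an estimated correlation for both). All 13 mitochondrially encoded genes were lower in batch 2, as were 22 of 30 genes of oxidative phosphorylation, with 4 higher, and 35 of 59 ribosomal protein genes, with 5 higher (adjusted p = 0.66, 0.35 and 0.835 with an estimated correlation). Adjusted over the list alone, 18 cholesterol synthesis genes were higher and 2 lower, and the lower genes were 10 of heat shock, 7 cytotoxic, 13 mitochondrially encoded, 24 of oxidative phosphorylation and 36 ribosomal.

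The remaining lists held few calls for bexarotene in siINT cells. There were 0 among 22 genes of the unfolded protein response, 30 of oxidative phosphorylation, 13 mitochondrially encoded, 59 ribosomal protein and 8 histone genes by edgeR, and camera adjusted p-values of 0.974, 0.473, 0.593, 0.0599 and 0.656. DNAJB1 rose (0.84) among 12 heat shock genes, EGLN3 fell (-0.74) among 26 of hypoxia and glycolysis, and ANGPTL4 rose (3.95) among 9 angiogenic genes. Of other cell types, 0 of 5 monocyte and 0 of 6 epithelial and fibroblast markers were called by edgeR. Erythroid markers summed to 0 to 0.265 CPM in batch 1 and 0.122 to 0.664 CPM in batch 2, monocyte markers to 7.56 to 13.5 and 4.82 to 6.05 CPM, B-cell markers to 33.6 to 69.6 and 48.2 to 92.9 CPM, epithelial and fibroblast markers to 69.4 to 80.1 and 160 to 178 CPM, and cytotoxic markers to 677 to 1430 and 408 to 675 CPM.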
